A study of Mus musculus with 6 samples.

How the data were processed

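The labels describe 6 samples of MC38 cells in 2 groups, parental and STING-N153S, with 3 samples in each. Libraries were made from RNA primed with oligo-dT carrying a sample barcode and a unique molecular identifier, and 3'-end fragments of the cDNA were amplified, per the labels' protocols. The deposited count table holds whole-number counts per gene, which the authors made with STAR 2.7.5b, Drop-seq tools 1.12 and Picard 2.18.26 on GRCm38 with GENCODE annotation M25 and no trimming, per the file headers. Whether the deposited counts are collapsed by molecular identifier, and how reads matching several genes were treated, is not given in the sources used here. If they are not collapsed, amplification adds to the spread, and every interval, floor and count test here covers counting error only.

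The 3 columns that the deposited annotation names as wild type, with replicate numbers, were matched to the 3 parental samples by genotype and number. The table has 6 further columns, which the deposited annotation names as 2 sets of 3 replicates, more than the 3 STING-N153S samples. No label says which set those samples are, so none of the 6 columns was mapped or used. The comparison fixed before the data were examined, STING-N153S against parental cells with edgeR's quasi-likelihood test, with camera on gene lists, was therefore not run, and no group difference is reported.

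The 31 gene lists were fixed before the data were examined, and 569 of their 653 members were analysed. Counts of list members in the text are out of the members analysed. All other choices reported were made after the data were examined, because the planned ones needed both groups: the measures, the count test between libraries, the ratios of gene pairs, the alternatives and the rule for named genes. That rule takes Sting1, the 3 members with the highest mean CPM of each of the first 10 lists and 2 of each other list, the 10 genes with the highest mean CPM, and the 10 with the largest ratio between libraries among varying genes with at least 100 counts. The last 2 parts take curated symbols only. Some genes that the rule takes are not reported here. Other genes in the text were picked after their values were seen, as examples of a list, members with 0 counts, or genes that a test concerned. Gene positions are those of RefSeq on GRCm38.p6.

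Counts were divided by the library total to give CPM. The floor is 3 counts, which is 0.893, 0.746 and 0.935 CPM in parental replicates 1 to 3 and 0.283 CPM over their 10588955 counts together. The table lists 24181 genes, of which 13746 had a count in all 3 libraries and 4383 in none. A mean of at least 1 CPM was reached by 11964 genes, 10 CPM by 7553, 100 CPM by 2064 and 1000 CPM by 131. The median of each list was set against 10000 random lists of the same size drawn from all genes, not matched on level. That percentile was 90.9 for type I interferon-stimulated genes, 38.1 for guanylate-binding and immunity-related GTPases, 97.4 for MHC class I, 18.3 for MHC class II, 16.4 for chemokines and cytokines, 98.5 for NF-kB targets, and 99.5 for the cGAS-STING pathway. Ratios of 2 genes within a library have exact (Clopper-Pearson) 95% intervals from the pooled counts.

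Variation between the parental libraries was tested by a chi-square test of counts, against expected counts proportional to library sizes scaled by median ratios, for genes with an expected count of at least 5 in each library, at a false discovery rate of 0.05. At an unadjusted p below 0.05, 1473 of 11118 genes passed. The test was run on simulated Poisson counts for 24181 genes with 200 changed in 1 library. It first used library totals and simulated changes that were all increases, and then failed; the cause was not tested. The scaling was changed to median ratios after that failure and after a first count with library totals, which was 286 genes against 310 now, and in the same step the simulated changes were made balanced, so the test passing does not show which of these mended it. In the final simulation 31.0% of genes changed 1.5-fold, 59.0% changed 2-fold and 85.0% changed 4-fold were recovered. False calls made up 1.59%, 3.28% and 7.10% of the calls, and the last is above the nominal rate. The biological coefficient of variation was estimated with edgeR 4.0.16 as a common dispersion with TMM scaling and an intercept only, and simulated values of 0.03 and 0.1 were returned as 0.0299 and 0.0996. The deposited annotation numbers the 3 libraries as biological replicates, and nothing used here says that they came from separate cultures. The p-values of the count test measure departure from counting noise between these samples, and that spread may be technical.

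Alternatives changed the scaling (TMM, median ratios from DESeq2 1.42.0, upper quartile, totals without the 20 highest genes), the minimum level, the count test and the libraries included. Other tools were R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.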

Results

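Gene expression was measured by bulk 3'-end RNA sequencing in MC38 cells, a mouse colon adenocarcinoma line grown in culture. The labels give 2 groups of 3 samples, parental MC38 cells and MC38 cells expressing STING-N153S, an amino acid substitution in STING, the endoplasmic reticulum protein that relays the sensing of cytosolic DNA to interferon and NF-kB signalling. The series compares parental with STING-N153S cells. The columns of the STING-N153S samples were not analysed here, because the names of the columns did not tie a single column to each of those samples, so no difference between the groups is reported. The 3 parental libraries, replicates 1 to 3, held 3358908, 4020023 and 3210024 counts and 16391, 16892 and 16224 genes with at least 1 count. Levels are CPM, the counts of a gene scaled to the library total, given as mean ± SD over these libraries (n = 3).

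The components of the cGAS-STING pathway were counted in parental MC38 cells. Sting1 itself (chromosome 18, 35733678 to 35740554, GRCm38) had 38, 44 and 47 counts, or 11.3, 10.9 and 14.6 CPM, with a mean of 12.3 ± 2.04 CPM (SD, n = 3). Cgas, the cytosolic DNA sensor that makes the ligand of STING, stood at 24.1 ± 2.51 CPM (SD, n = 3), and its count was above that of Sting1 in 3 of 3 libraries, at a ratio of 2.01 ± 0.47 (SD, n = 3). The ratio was 2.34, 2.23 and 1.47 in replicates 1 to 3. Its exact 95% interval over the pooled counts, which covers counting error only, ran from 1.60 to 2.47. That interval bounds the pooled ratio, so it does not tell whether replicate 3, which lay below it, differed beyond counting error. Tbk1, the kinase that STING recruits, had 23.1 ± 0.88 CPM and Irf3, the transcription factor it phosphorylates, 23.9 ± 2.87 CPM (SD, n = 3). Ikbke, the kinase related to Tbk1, had 0.978 ± 0.417 CPM (SD, n = 3), and the count of Tbk1 exceeded it in 3 of 3 libraries. A 3'-end count does not read the N153S position, and it would miss a transgene that lacks the 3' end of the native transcript.

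Of the 24 members of the pathway list that were analysed, 22 had a mean of at least 1 CPM and 15 of at least 10 CPM. The highest were genes of protein transport, Tmed2 with 250.5 ± 4.55 CPM and Surf4 with 206 ± 9.66 CPM (SD, n = 3), followed by Slc19a1, a folate carrier that also takes up cyclic dinucleotides, with 90.1 ± 2.26 CPM (SD, n = 3). Enpp1, which hydrolyses the STING ligand, had 0 counts, which by counting error alone allows up to 0.283 CPM over the 3 libraries. That bound does not cover reads lost in assignment, since how reads matching several genes were treated is not given. Of 21 members tested, 1 varied between the parental libraries beyond counting noise, Lrrc8c, a subunit of the volume-regulated anion channel, which had 22.7 ± 7.10 CPM (SD, n = 3).

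**Figure D1:**
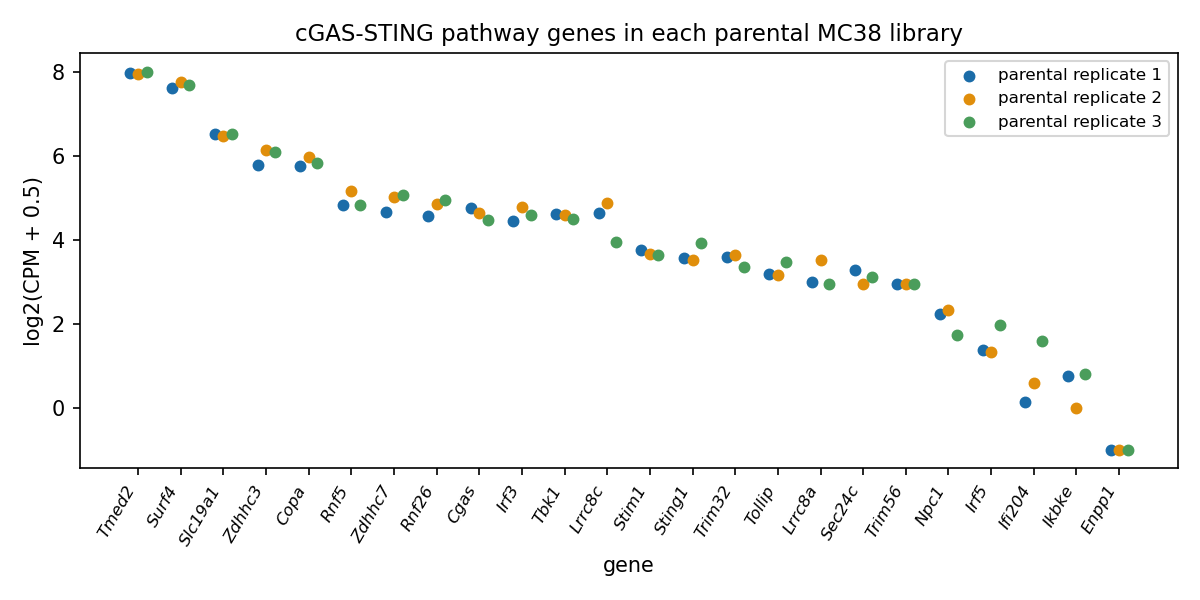
CPM of the genes of the cGAS-STING list in each parental library, plotted as log2(CPM + 0.5), with 1 point per library and genes ordered by mean CPM. The mean CPM is above 200 for Tmed2 and Surf4 and 12.3 for Sting1, and Enpp1 has 0 counts.

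Type I interferon-stimulated genes were counted over a wide range in parental cells. Of 48 members analysed, 38 had a mean of at least 1 CPM, 12 of at least 10 CPM and 2 of at least 100 CPM. Those 2 were Ifitm3, which restricts virus entry, with 481 ± 12.2 CPM, and Bst2 (tetherin), with 157 ± 2.96 CPM (SD, n = 3). Samhd1, a dNTP hydrolase, had 54.2 ± 3.30 CPM, Ifit2 25.4 ± 0.88 CPM and Isg15, a ubiquitin-like modifier, 20.4 ± 2.54 CPM (SD, n = 3). The transcription factor Irf7, with 4.49 ± 2.05 CPM (SD, n = 3), stood lower than these in mean CPM. Mx2, Oas2 and Oas3 had 0 counts, which by counting error alone allows up to 0.283 CPM. The median member stood at 3.16 ± 0.59 CPM (SD, n = 3). The median of the members' mean CPM, 3.29, was at the 90.9th percentile of random gene lists of the same size. Those lists were drawn from all genes, also genes without a count, and were not matched on level. Of 33 members tested, 0 varied between the libraries.

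In the list of guanylate-binding proteins and immunity-related GTPases, products of interferon-gamma-inducible genes, 7 of 15 members had a mean of at least 1 CPM. The list also holds Irf1, which is not a GTPase and is among the 7. Irf1, a transcription factor induced by interferon gamma, led the list with 33.9 ± 3.96 CPM, followed by Irgm1 with 13.5 ± 1.86 CPM and Gbp2 with 11.02 ± 1.85 CPM (SD, n = 3). Of the 14 genes of the interferon and receptor list, 5 were analysed, which are receptors and were all at 1 CPM or more. The receptor subunits for interferon gamma, Ifngr2 at 66.1 ± 0.22 CPM and Ifngr1 at 52.8 ± 3.48 CPM (SD, n = 3), were the highest, and Il10rb had 14.6 ± 1.09 CPM (SD, n = 3). The type I receptor subunits Ifnar2 and Ifnar1 had 14.1 ± 1.73 and 9.24 ± 2.699 CPM (SD, n = 3), and the count of Ifngr1 exceeded that of Ifnar1 in 3 of 3 libraries, at a ratio of 6.13 ± 2.21 (SD, n = 3).

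Of 21 MHC class I antigen presentation genes analysed, 17 had a mean of at least 1 CPM, 11 of at least 10 CPM and 5 of at least 100 CPM. The chaperone Pdia3 had 905 ± 14.1 CPM, the light chain B2m 399 ± 7.95 CPM and the heavy chain H2-D1 316 ± 14.6 CPM (SD, n = 3). The count of H2-D1 was above that of the other classical heavy chain, H2-K1, in 3 of 3 libraries, at a ratio of 5.79 ± 1.25 (SD, n = 3). These heavy chains are similar in sequence, and how reads matching both were counted is not given in the sources used here, so the ratio is uncertain. The immunoproteasome subunits Psmb8, at 102 ± 6.84 CPM, and Psmb10, at 73.7 ± 0.66 CPM, stood beside 1.53 ± 0.93 CPM of their partner Psmb9 (SD, n = 3). Nlrc5, the transactivator of class I genes, and H2-Q7 had 0 counts. The unknown handling of reads that match several genes applies here too, so 0 counts do not show that the RNA was absent. Of the class II list, 2 of 6 members reached 1 CPM, H2-DMb1 with 4.12 ± 0.58 CPM and H2-DMa with 3.33 ± 0.31 CPM (SD, n = 3), and the invariant chain Cd74 had 0.390 ± 0.203 CPM (SD, n = 3).

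Of 23 chemokine and cytokine genes, 8 had a mean of at least 1 CPM. The monocyte attractants Ccl2, with 135 ± 4.76 CPM, and Ccl7, with 88.4 ± 9.82 CPM, were the highest, followed by Ccl5 with 49.9 ± 2.35 CPM (SD, n = 3). Csf1, the macrophage growth factor, had 46.3 ± 5.59 CPM, Cxcl1 22.4 ± 2.21 CPM and the interferon-inducible Cxcl10 21.7 ± 1.43 CPM (SD, n = 3). Cxcl9, Cxcl16, Il6, Csf2 and Csf3 had 0 counts, which by counting error alone allows up to 0.283 CPM each. NF-kB targets were counted more widely, with 21 of 22 members at 1 CPM or more and 5 at 100 CPM or more. The inhibitor Nfkbia had 444 ± 9.46 CPM, Ier3 198 ± 8.84 CPM and the mitochondrial superoxide dismutase Sod2 117 ± 7.21 CPM (SD, n = 3). The adhesion gene Icam1 had 0 counts and Vcam1 113 ± 14.6 CPM (SD, n = 3).

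Stress and death genes covered a wide range. All 25 members analysed of the unfolded protein and integrated stress response list were at 1 CPM or more, led by the endoplasmic reticulum chaperones Hspa5, with 1460 ± 24.9 CPM, Hsp90b1, with 1271 ± 51.0 CPM, and Calr, with 650 ± 55.9 CPM (SD, n = 3). Of 25 cell death regulators, 20 were at 1 CPM or more, among them Bax (264 ± 5.80 CPM) and Mcl1 (126 ± 10.97 CPM; SD, n = 3), while the inflammasome sensors Nlrp3 and Aim2 had 0 counts. Of 18 p53 targets, 15 were at 1 CPM or more, with Plk2 at 301 ± 27.1 CPM and the cell cycle inhibitor Cdkn1a at 40.5 ± 1.07 CPM (SD, n = 3). Calcium handling genes of the endoplasmic reticulum reached 1 CPM in 14 of 15 members, with the chaperone Canx at 688 ± 32.1 CPM (SD, n = 3).

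The highest list medians were those of cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation (378 ± 4.77 CPM), MYC targets (279 ± 9.12 CPM) and the cell cycle (155 ± 5.33 CPM; SD, n = 3). All 34 cell cycle and DNA replication genes were above 10 CPM, 27 of them at 100 CPM or more, led by the kinesin Cenpe with 882 ± 16.6 CPM and the ribonucleotide reductase subunit Rrm2 with 586 ± 7.14 CPM (SD, n = 3). All 20 MYC and ribosome biogenesis genes were at 1 CPM or more, with Ncl at 2523 ± 160 CPM and Npm1 at 2225 ± 10.6 CPM (SD, n = 3). The median of the 34 cytosolic ribosomal protein genes was 1706 ± 11.7 CPM (SD, n = 3), with Rpl37 at 4174 ± 129 CPM (SD, n = 3). All 33 nuclear-encoded oxidative phosphorylation genes analysed were above 10 CPM, led by Atp5b (1647 ± 29.9 CPM) and Cox8a (1510 ± 28.9 CPM; SD, n = 3). Of the 20 glycolysis and hypoxia genes, all at 1 CPM or more, Ldha had 3401 ± 19.8 CPM and Pkm 1565 ± 45.1 CPM (SD, n = 3). The 21 cholesterol genes were all at 1 CPM or more, led by Cyp51 with 265 ± 7.41 CPM and Msmo1 with 220.2 ± 5.50 CPM (SD, n = 3). Of 29 autophagy and lysosome genes, 28 were at 1 CPM or more, led by Ctsl with 890 ± 28.6 CPM and Lamp1 with 581 ± 32.5 CPM (SD, n = 3). The 16 NRF2 and antioxidant genes were all at 1 CPM or more, with the ferritin heavy chain Fth1 at 4887 ± 149 CPM and Prdx1 at 1806 ± 22.9 CPM (SD, n = 3).

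Of 18 immediate early genes, 16 were at 1 CPM or more, led by the AP-1 subunits Fosl1 with 665 ± 36.3 CPM and Jun with 482 ± 25.5 CPM, while Fos had 0.369 ± 0.112 CPM (SD, n = 3). Of 12 immune checkpoint and NK ligand genes, 8 were at 1 CPM or more, led by Cd47, whose product signals against phagocytosis, with 186 ± 8.68 CPM, and Pvr with 41.4 ± 8.79 CPM (SD, n = 3). Cd274, which encodes PD-L1, had 1.11 ± 0.33 CPM (SD, n = 3).

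Among genes of cell identity, mesenchymal genes had higher counts than intestinal epithelial markers. Of 28 extracellular matrix and mesenchymal genes, 23 were at 1 CPM or more, led by the intermediate filament gene Vim with 3058 ± 176 CPM and Sparc with 545 ± 26.1 CPM (SD, n = 3). Of 20 intestinal epithelial markers listed, 8 were analysed and 1 reached 1 CPM, Axin2 with 2.19 ± 0.27 CPM, and Krt7 had 0.104 ± 0.180 CPM (SD, n = 3). Of 8 fibroblast markers, 5 reached 1 CPM, led by Col3a1 with 115 ± 8.80 CPM and Dcn with 52.1 ± 5.48 CPM (SD, n = 3). Myeloid markers reached 1 CPM in 1 of 10 members analysed of 16 listed, Cd14 with 22.1 ± 0.80 CPM, and Cd68 had 0.925 ± 0.324 CPM (SD, n = 3). Without replicate 1 the number of myeloid markers at 1 CPM or more was 2. None of the 6 lymphocyte markers analysed of 16 listed (Lck 0.104 ± 0.180 CPM, Gzma 0.0992 ± 0.172 CPM) and none of the 6 endothelial markers analysed of 10 listed (Esam 0.385 ± 0.185 CPM, Pecam1 0.182 ± 0.160 CPM; SD, n = 3) reached 1 CPM. Of the 4 melanocyte markers analysed of 8 listed, 2 reached 1 CPM, Gpnmb with 58.5 ± 5.98 CPM and Mitf with 1.18 ± 0.76 CPM (SD, n = 3). Mitf had 5, 7 and 1 counts, and without replicate 2 the number of melanocyte markers at 1 CPM or more was 1. Both sex-linked genes analysed, Xist and Ddx3y, had 1 count each over the 3 libraries.

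**Figure D2:**
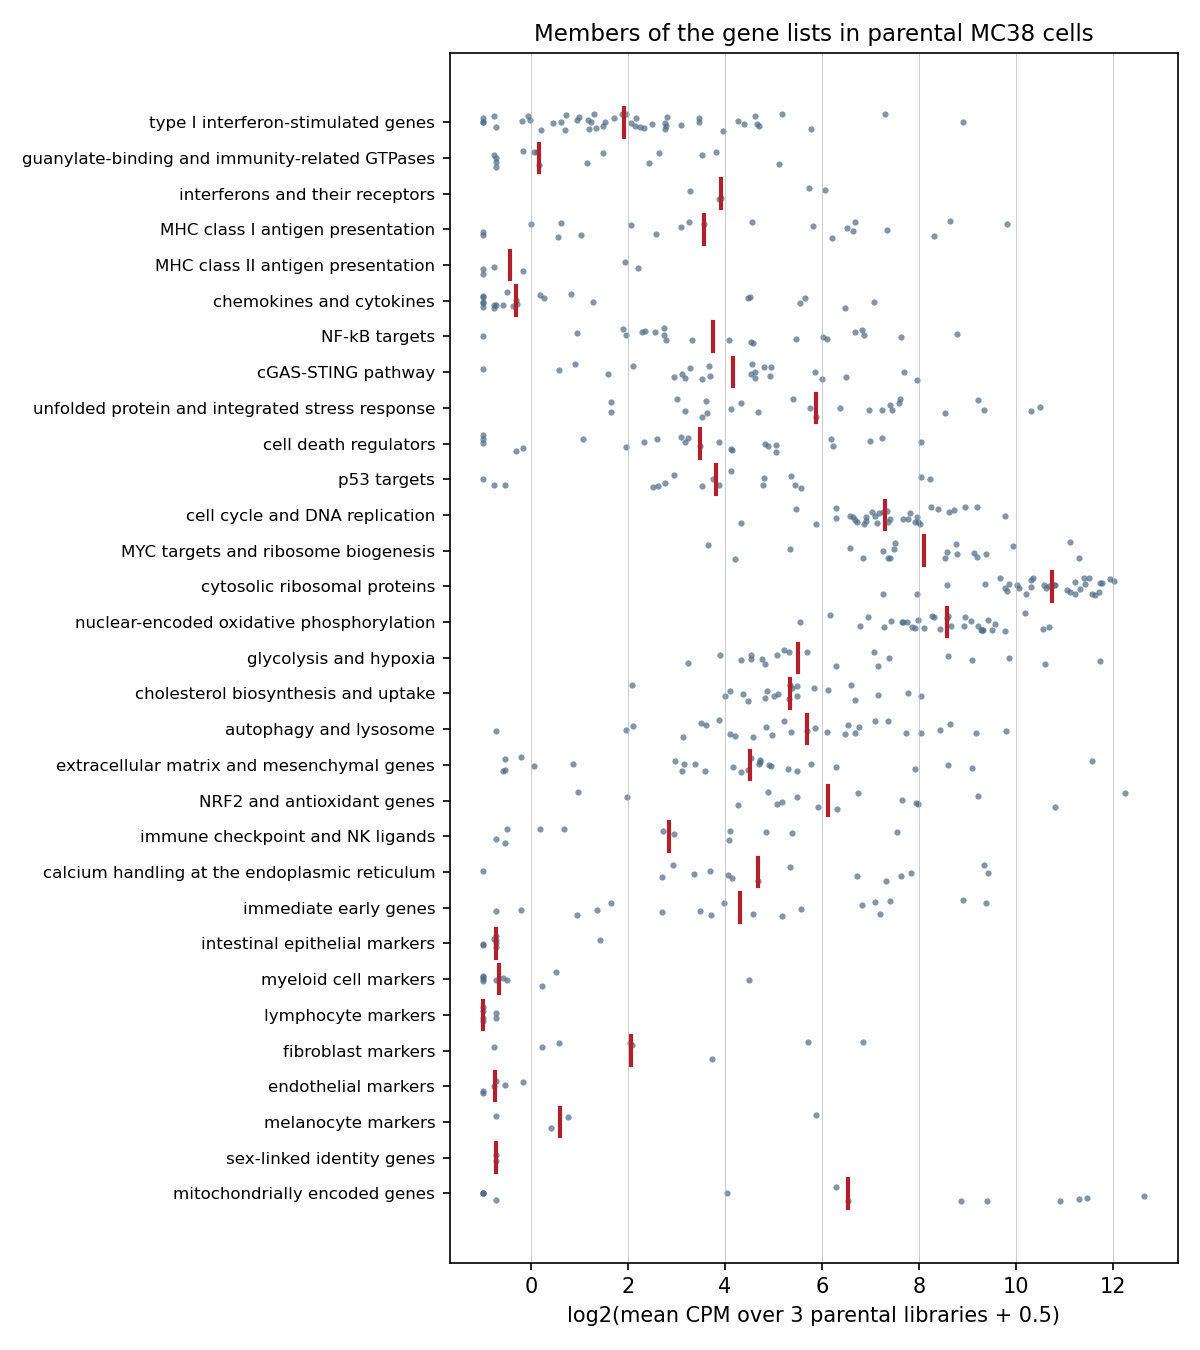
Mean CPM of every member analysed of the 31 gene lists over the 3 parental libraries, plotted as log2(mean CPM + 0.5), with 1 point per gene and a red bar at the median of each list. The cytosolic ribosomal protein list has the highest median, 1706 CPM, and the median lymphocyte marker has 0 CPM.

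The most abundant transcript with a curated symbol was Lgals1, a galectin, with 7324 ± 178 CPM (SD, n = 3). The ribosomal RNA gene CT010467.1, which has no curated symbol, was above it. That gene took 1.46%, 1.30% and 1.30% of the counts of replicates 1 to 3 and is part of the library totals. Other highly counted transcripts were the mitochondrial ribosomal RNA mt-Rnr2 (6463 ± 234 CPM), the thioredoxin gene Txn1 (5787 ± 680 CPM), Rps26 (5141 ± 258 CPM), Fth1, the actin gene Actb (4649 ± 176 CPM), Rpl37, the phosphatase subunit Ppp1ca (3806 ± 151 CPM) and S100a6 (3608 ± 118 CPM; SD, n = 3). Of 13 mitochondrially encoded genes analysed, 9 were at 1 CPM or more, with mt-Rnr1 at 2823 ± 463 CPM (SD, n = 3). The 20 highest genes took 9.56%, 9.05% and 9.03% of the counts of replicates 1 to 3.

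The parental libraries were then compared with each other, which compares libraries and not conditions. Of 39 replication-dependent histone genes tested, 13 varied beyond counting noise, 11 of them lower in replicate 3 than in both others and 2 higher. H4c4 stood at 533 and 535 CPM in replicates 1 and 2 and at 24.3 CPM in replicate 3, H2ac4 at 57.2, 63.7 and 1.56 CPM, and the linker histone H1f4 at 372, 390.0 and 97.8 CPM. H1f3 (102, 132 and 17.8 CPM), H2ac20 (125, 125 and 38.0 CPM), H2ac13 (35.4, 39.1 and 14.0 CPM) and H2bc11 (16.1, 17.7 and 2.80 CPM) were also lower in replicate 3. H2ac8 and H3c3 were the 2 that were higher there, with H2ac8 at 475, 442 and 589 CPM. Of the lists fixed beforehand, cytosolic ribosomal proteins varied in 14 of 34 members and mitochondrially encoded genes in 6 of 9, and 0 of 34 cell cycle and DNA replication genes varied. The test detects smaller differences in genes with more counts, and the list medians were 1706 CPM (ribosomal) and 155 CPM (cell cycle). These numbers therefore do not rank the lists by stability. The summed CPM of the ribosomal list was 65228 ± 679 (SD, n = 3). The other genes among the 10 largest ratios were Igfbpl1 (54.5, 55.0 and 9.03 CPM), the noncoding RNA Rn7sk (38.7, 27.4 and 10.3 CPM) and the Y RNA Rny3 (30.1, 37.1 and 11.8 CPM).

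**Figure D3:**
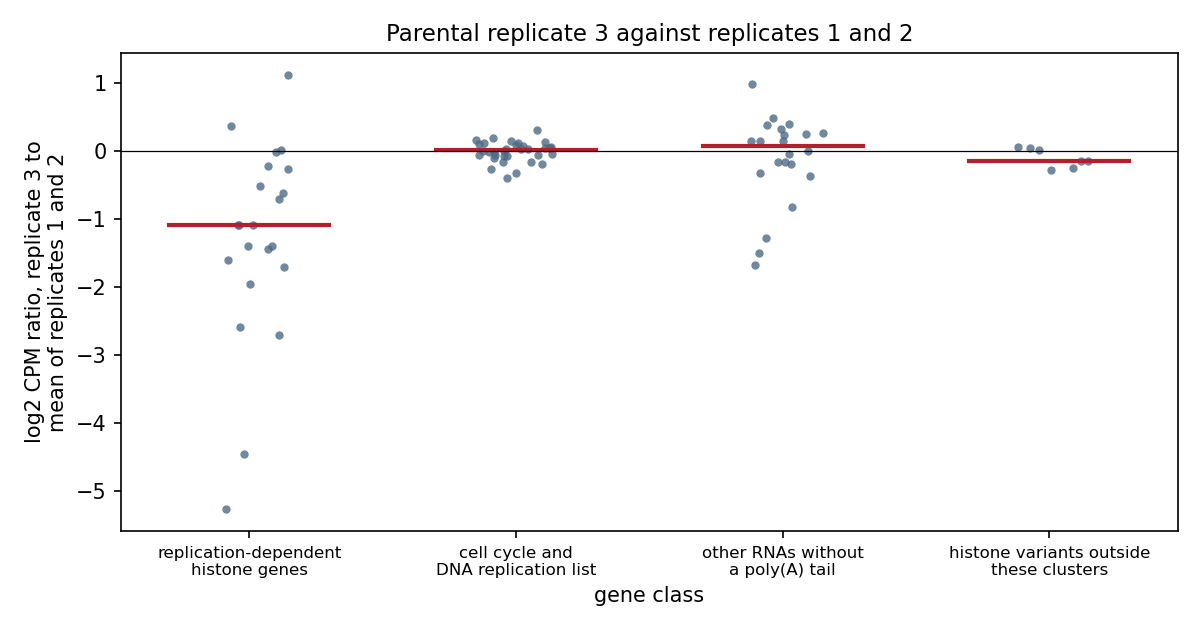
Log2 ratio of CPM in parental replicate 3 to the mean of replicates 1 and 2 for genes of 4 classes, with 1 point per gene and a red bar at the median. The median is -1.10 over 22 replication-dependent histone genes and 0.0085 over 34 cell cycle and DNA replication genes.

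Across all genes, 310 of 11118 tested (2.79%) varied between the 3 libraries beyond counting noise by a chi-square test of counts with Benjamini-Hochberg adjustment, and 226 of them differed by under 1.5-fold between the highest and the lowest library. Replicate 3 was the farthest from the others in 193 of these genes, replicate 1 in 73 and replicate 2 in 44. Without replicate 3, 59 genes differed. Pairs of libraries differed in 59 genes (replicates 1 and 2), 232 genes (1 and 3) and 220 genes (2 and 3), so that no pair agreed within sampling noise, and each library was counted as 1 replicate. The common biological coefficient of variation was 0.0552 over 9528 genes, and 0.0318 without replicate 3.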

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

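All tests and alternatives in this part were chosen after the data were seen. The other normalizations, filters, tests and covariates fixed beforehand for the STING-N153S comparison were not run, since no column was mapped to the STING-N153S samples. No paired analysis was possible because only the parental group was analysed.

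Leaving out 1 library gave 59 to 232 genes varying between parental libraries and a biological coefficient of variation of 0.0318 to 0.0688. The lowest of each came without parental replicate 3 (59 genes against 310, and 0.0318 against 0.0552). Fewer libraries also give the test less to detect. Other settings gave 282 to 322 varying genes, among them 286 with library totals only, 300 with pairwise exact binomial tests and 290 without replication-dependent histone genes. The number of genes at a mean CPM of 1 or more, 11964, ran from 10673 at a minimum of 2 CPM to 13381 at 0.5 CPM. Sting1 ran from 11.1 CPM without replicate 3 to 13.5 CPM with totals that leave out the 20 highest genes.

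Of 344 values for single named genes under other scalings, 289 moved by less than 1 SD. The 55 that moved more did so with totals that leave out the 20 highest genes, which raises the CPM of every gene left in. The factors of the other scalings lay between 0.984 and 1.02, so a mean could hardly move by 1 SD under them. The 289 therefore do not show that these genes are stable. Leaving out 1 of 3 libraries cannot move a mean by 1 SD, so that measure says nothing of single genes there, and the mean CPM of H4c4 went from 364 to 534 without replicate 3. Of 279 counts of list members at or above the minimum, 62 of them at a minimum changed to 0.5 or 2 CPM, 274 stayed within 1.5 times the main count. The 5 others concern myeloid markers (1 member, against 3 at 0.5 CPM, 2 without replicate 1 and 2 with totals that leave out the 20 highest genes) and melanocyte markers (2 members, against 1 at 2 CPM and 1 without replicate 2). Depth limits single genes below about 1 CPM, where a library's floor of 3 counts lies between 0.746 and 0.935 CPM.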

Other observations

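The S-phase test and the test of RNA without a poly(A) tail were chosen after at least part of their results had been seen, and those of A stretches and of shared mitochondrial sequence before theirs, though both patterns were found in these counts. The labels give the parental libraries no difference, and the share of cells in S phase was the only biological explanation tested.

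Replication-dependent histone genes were lower in parental replicate 3, with a median log2 ratio to the mean of replicates 1 and 2 of -1.10 over the 22 genes with at least 60 counts in all (95% bootstrap interval -1.58 to -0.52), and 19 of 22 below 0. The bootstrap intervals given here come from resampling genes, so they do not measure the spread between libraries, and replicate 3 is 1 library. The 7 histone variants outside these clusters had a median of -0.15 (interval -0.26 to 0.03), with 4 below 0. Fewer cells in S phase would lower replication genes too, but the cell cycle and DNA replication list had a median of 0.0085 (interval -0.07 to 0.04) over 34 genes, which argues against that as the whole cause, although the list also holds mitotic genes. A lower yield of RNA without a poly(A) tail could lower histone messages, and it stays open. The 22 other such RNAs with at least 60 counts had a median of 0.067 (interval -0.19 to 0.24). Of these, 11 were below 0, among them Rn7sk and Rny3, and 11 above. Their median log2 ratio of replicate 1 to replicate 2 was 0.26, against -0.066 for the histone genes. Replicates 1 and 2 were thus themselves less alike for these RNAs. The bound for the test of these RNAs was made stricter after its value of 0.067 was seen. Under the first bound, which ignored the interval, the same value counted against the explanation, by a margin between the quartiles of -0.30 and -0.34 that was judged too thin. Priming at internal A stretches may differ between libraries and also stays open, since the longest A run did not separate the 22 histone genes by their ratio (Spearman rho across genes 0.0543, permutation p 0.818), and no run exceeded 8 bases.

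The 4 mitochondrially encoded genes, mt-Atp6, mt-Co2, mt-Co3 and mt-Nd3, had at most 3 counts in all, beside 26626 counts of mt-Cytb and 20466 of mt-Nd1. Near-identical nuclear copies may take or remove their reads. The 50-base words in the last 300 bases of the GENCODE M21 transcripts were looked up in other genes. Over these 4 genes, a median of 99.2% of the words also occurred in another gene. The median over 6 mitochondrial genes with at least 1000 counts was 0%, and the highest of them, mt-Nd2, shared 31.9%. Against a simple reading, mt-Co1 shared 100% and still had 979 counts, and few reads were counted in the copies analysed, with 80 counts for Gm28438, 45 for Gm13341, 8 for Gm13340, 6 for Gm28437, 3 for Gm28661, and 1 each for Gm10925 and Gm29216. Another copy of mt-Atp6 was not analysed here. Low counts of these genes are therefore uncertain as a measure of their RNA.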
